A study of Eohaustorius estuarius with 16 samples.

How the data were processed

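Whole-body RNA of the amphipod Eohaustorius estuarius was measured on 16 single-colour Agilent arrays, 8 from animals kept on solvent-spiked sediment and 8 from animals kept on sediment spiked with cyfluthrin. Groups and replicate numbers were taken from the sample titles. Each array carried 15744 spots, of which 15208 were not control spots, and these represented 8507 probes, each assigned to its own contig of an assembled amphipod transcriptome. The files do not pair the contigs with gene names, so contigs are given by identifier. For the same reason the 22 gene lists fixed before the data were examined (detoxification enzymes, chaperones, ion channels, cuticle and others) could not be used, and their alternative settings were not run.

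The deposited scanner files give spot intensity on a linear scale. Per the file headers, images were read with Agilent Feature Extraction 10.7.3.1, which subtracted background and removed spatial trends to give the processed signal; the submitters' processing notes name version 9.1 of the same program. Per the labels' protocols, total RNA was purified on columns by all laboratories but 1 and labelled with Cy3 by a low-input amplification kit. The authors' value table holds log2 values of the same arrays, with 8567 probes including controls. Set against the scanner values, each of its 16 columns matched its own array best, with correlations across probes of 0.692 to 0.987 and slopes of 0.756 to 1.09. The lowest correlation and slope were both those of cyfluthrin replicate 7, and the next lowest correlation was 0.936 (cyfluthrin replicate 2). Its probes are centred on their median over the 16 arrays, its column medians lie between −0.056 and 0.082, and the normalization behind it is not given in the sources used here. Outlier flags of the deposited files are scanner calls per spot.

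From the deposited intensity, each array's processed signal was scaled so that its 75th percentile over non-control spots equalled the mean of the 16 arrays (455 units). Values under a floor of 5 scaled units were set to it, log2 was taken, and spots of a probe were averaged. Between 30 and 88 spots per array carried an outlier flag and were left out, and no spot was saturated. A probe counts as above background on an array when a share of at least 0.5 of its spots was called well above background, and a probe was tested when this held on at least 4 of the 8 arrays of either group, which left 7552 probes. Log2 values were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with group as the only term, and a probe was called changed at a Benjamini-Hochberg adjusted p under 0.05. Differences in a single measure per array were tested by exact two-sided permutation of the 16 arrays. A change against a group in which no array was above background is given as a lower bound, with each dim value replaced by the lowest signal above background on that array where this was higher.

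In a simulation of the comparison with 7552 probes and 8 arrays per group, the fit recovered 14% of probes changed by 0.5 log2 units, 54% at 1, 88% at 2 and 98% at 4, with 5 false calls. With the changed probes left out of the simulated data, no probe was called. Simulated noise was independent between probes, with the same SD in both groups and no slide effect. False calls in the real data may therefore differ. The number of arrays limits the precision of all values.

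The comparison, its filter, the alternatives of normalization, filter, slide, pairing, weights, threshold, test and left-out arrays, and the rule for named contigs were set before the data were examined. The rule names the 2 unnamed contigs with the largest rise and the 2 with the largest fall among those past the threshold. The files hold no mean-pixel signal, so the normexp background correction (offset 50) was run on median-pixel signals in place of the mean-pixel signals that had been planned. Floors of 1 and 20 units, the left-out arrays and the permutation within slides for the similarity of replicates, and the cutoff of 8-fold used to describe a set of rising probes were chosen after the data had been seen.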

Results

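Arrays of amphipods exposed to cyfluthrin differed from control arrays in 2 ways. A set of 27 contigs rose in signal by 8-fold or more together, a limit chosen after the values were seen. Smaller changes went in both directions, with 71 further contigs rising and 112 falling. Slide row went with treatment throughout, so effects of the 2 cannot be told apart. Eohaustorius estuarius is a burrowing estuarine amphipod used in sediment toxicity tests, and cyfluthrin is a pyrethroid, an insecticide class that acts on voltage-gated sodium channels. Animals were held for 10 days on sediment with a nominal 1.6 µg/kg cyfluthrin or on solvent-spiked sediment. The series asks how comparable array data are between 6 laboratories, and the 16 whole-body arrays of laboratory A, 8 per group, are described here. The arrays lay on 2 slides, each with 4 control and 4 cyfluthrin arrays. Between 6234 and 8478 of the 8507 probes were above background on an array. The highest count was that of cyfluthrin replicate 7, which also had the brightest negative control spots, and the next highest was 7792. The 75th percentile of signal was 440 ± 116 units in controls and 470 ± 219 in cyfluthrin arrays (SD, n = 8 each; exact permutation p = 0.771).

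Of 7552 probes tested, 98 rose and 112 fell with cyfluthrin (limma, adjusted p under 0.05), and 1183 had an unadjusted p under 0.05. Contig eohaus_trim.v2-contig_3691 had the largest rise, from a log2 signal of 6.95 ± 0.997 in controls to 11.24 ± 1.48 with cyfluthrin (SD, n = 8 each; limma). This was a log2 change of 4.29 (SE 0.59, 95% interval 3.02 to 5.55, limma adjusted p = 0.000347), or 19.5-fold. Contig eohaus_trim.v2-contig_6271 rose from 4.71 ± 1.05 to 8.93 ± 1.40, a log2 change of 4.22 (SE 0.58, limma adjusted p = 0.000347), and was above background on 5 of the 8 control arrays. The largest fall was in contig eohaus_trim.v2-contig_2561, from 11.30 ± 0.35 to 8.68 ± 0.36, a log2 change of −2.62 (SE 0.18, limma adjusted p = 3.30e-07). Contig eohaus_trim.v2-contig_2087 fell from 10.17 ± 0.28 to 7.70 ± 0.23, a log2 change of −2.47 (SE 0.14, limma adjusted p = 2.62e-08). In all 4 contigs every cyfluthrin array lay on the same side of every control array. The rises were smaller from median-pixel signals corrected with normexp (offset 50), settings that differ in several steps at once: eohaus_trim.v2-contig_6271 rose by 2.27 (quantile normalization) and 2.22 (75th percentile) log2 units, and eohaus_trim.v2-contig_3691 by 3.54 and 3.50.

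**Figure D1:**
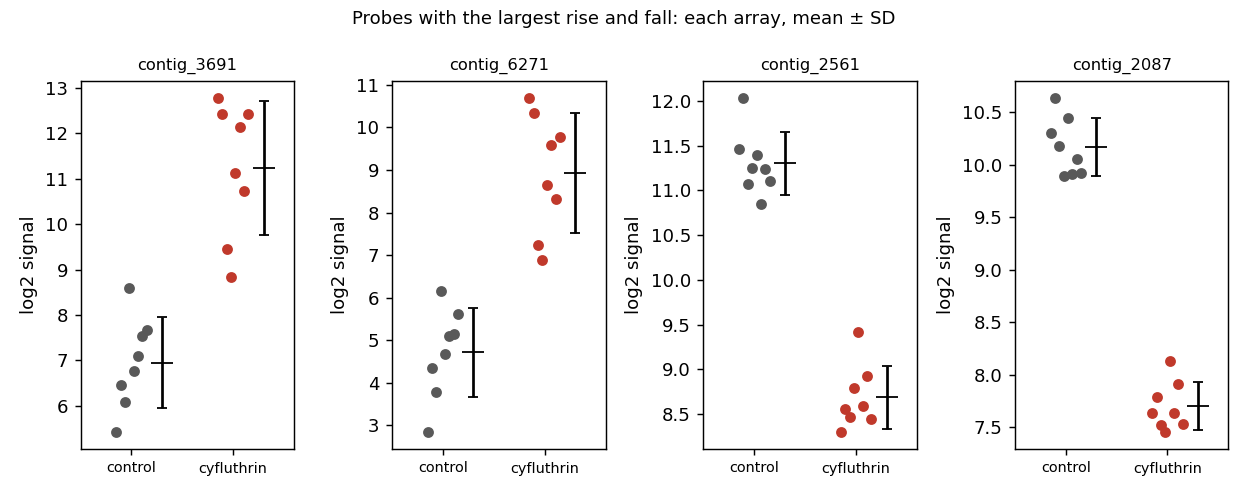
Normalised log2 signal of the 2 contigs with the largest rise and the 2 with the largest fall, each point an array (8 control, 8 cyfluthrin) and each bar the mean ± SD. The groups do not overlap in any of the 4 panels. Within the cyfluthrin group, the contigs that rose spread more (SD 1.48 and 1.40) than those that fell (SD 0.36 and 0.23). The same held within controls (SD 0.997 and 1.05 against 0.35 and 0.28).

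A set of rises stood apart from the rest, with its limit of 8-fold chosen after the values were seen. The 27 probes that rose by at least 8-fold had log2 changes of 3.01 to 4.29, with a median of 3.74, and the next largest rise was 2.42. With normexp on median-pixel signals, 11 (quantile normalization) and 10 (75th percentile) probes rose by at least 8-fold, and 27 and 25 of the set were still called higher. Averaged over these 27 probes, the log2 signal was 6.42 ± 0.64 in controls and 10.17 ± 1.12 with cyfluthrin (SD, n = 8 each), a 13.4-fold difference. Single arrays ranged from 5.48 to 7.42 in controls and from 8.60 to 11.53 with cyfluthrin. All 27 probes were above background on all 8 cyfluthrin arrays, 20 were so on all 8 control arrays and 2 on none, and with those 2 at their lower bound the median change was 3.73. In all 27 the groups did not overlap, which selection for a large change favours; chance gives it in 0.0155% of unselected probes.

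The other 71 rising probes had a median log2 change of 0.71 (1.63-fold); 20 of them rose by at least 2-fold and 19 had groups that did not overlap. The 112 falling probes had a median change of −0.81, 32 fell by at least 2-fold, and 38 had groups that did not overlap. Probes that fell were bright in controls, with a median log2 level of 10.15 against 7.28 over all probes tested. Across all probes tested, the dimmest 1888 had a median log2 change of 0.35 and the brightest 1888 of −0.07, and without cyfluthrin replicate 7 these were 0.19 and −0.05. Of the 71 smaller rises, 9 lay among these dimmest probes and 24 among the brightest, against 0 and 68 of the 112 falls. A dim probe lies near the floor and has little room to fall, so brightness need not be a trait of the falling contigs. Across 3 probes, 2 of them in the set of 27, signal was above background on all 8 cyfluthrin arrays and on no control array. Their rises were at least 4.78-fold to at least 12.2-fold (limma adjusted p from 1.62e-05 to 0.00115). The opposite was seen in 0 probes but could hardly occur, since 8478 of 8507 probes were above background on cyfluthrin replicate 7.

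**Figure D2:**
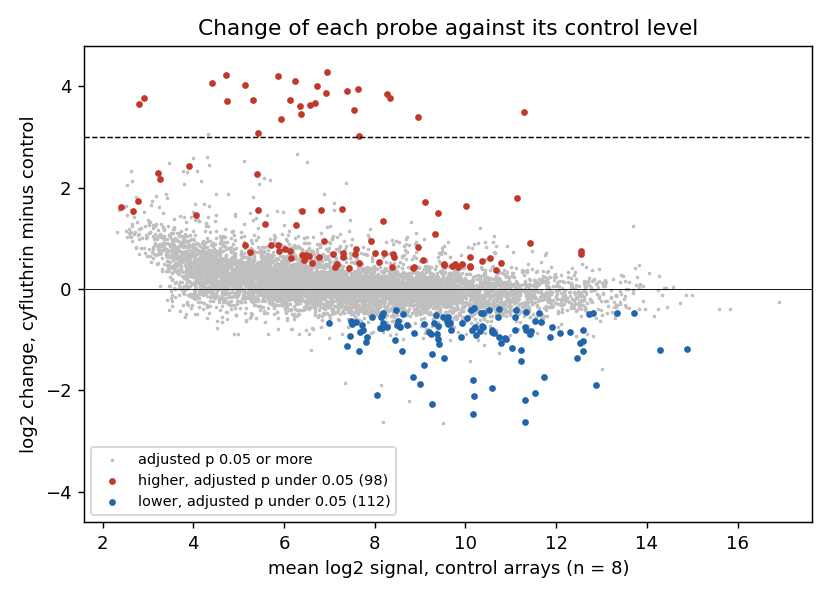
Log2 change (cyfluthrin minus control) of each of the 7552 probes tested against its mean log2 signal on the 8 control arrays, with probes at an adjusted p under 0.05 in red (98 higher) and blue (112 lower). The dashed line marks 8-fold, above which 27 of the red probes lie, and the blue probes sit at bright control levels (median 10.15).

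The split between rises and falls depended on the scaling. Rises made up 46.7% of calls, against 30.5% (46 of 151) when arrays were scaled on their median, 40.4% (92 of 228) with quantile normalization and 53.7% (117 of 218) with the 75th percentile of probes above background on all arrays. These scalings moved the median change of all probes from 0.12 to −0.06. With normexp on median-pixel signals, the share was 36.6% (106 of 290) after quantile normalization and 53.2% (42 of 79) with the 75th percentile. Of the 98 rises and 112 falls, 45 and 87 were still called with median scaling, and 42 and 37 with normexp and the 75th percentile. Leaving out control replicate 6 lowered the count of changed probes from 210 to 138 (71 falling), and leaving out control replicate 3 lowered the falling ones from 112 to 73.

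The slides differed in how many probes passed the threshold. With the slide as a block 347 probes changed (144 rose, 203 fell), among them all 210. Within slide 1 alone, with 4 arrays per group, 12 passed (3 rose, 9 fell) and 796 had an unadjusted p under 0.05; within slide 2 these were 195 (148 rose, 47 fell) and 1204. Of the 195 called on slide 2 alone, 166 had the same direction on slide 1 and 75 of these an unadjusted p under 0.05 there; without the set of 27 these were 139 and 48 of 168. Of the 12 called on slide 1, 12 had the same direction on slide 2, 11 with an unadjusted p under 0.05. Over all probes, 68.1% had the same direction on both slides. The set of 27 rose by a mean of 4.01 on slide 1 and 3.49 on slide 2 (log2); all 27 had an unadjusted p of at most 0.00552 on slide 1 by limma, where 1 passed the adjusted threshold, and all 27 passed on slide 2. On slide 1 the 2 named rising contigs had log2 changes of 4.23 and 4.50 with limma adjusted p of 0.231 and 0.192. A slide by treatment term was past the adjusted threshold in 0 of 7548 probes by limma. An unadjusted p under 0.05 was found in 241, fewer than the 1 in 20 that chance gives. With 4 arrays per group on each slide, this does not show that the slides agree.

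**Figure D3:**
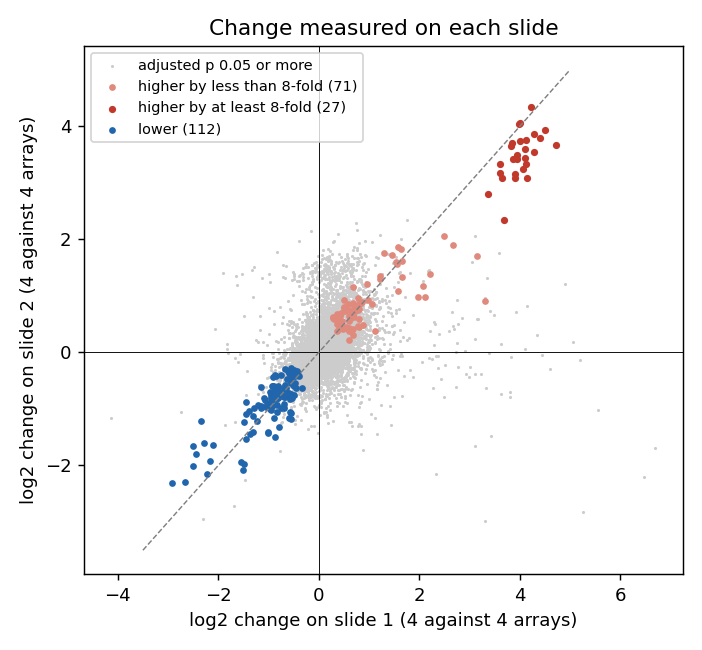
Log2 change (cyfluthrin minus control) of each probe on slide 1 against that on slide 2, 4 arrays per group on each, with called probes coloured by group. Called probes were selected on both slides together, which favours agreement, and the 27 that rose by at least 8-fold stand apart at the upper right.

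Control arrays correlated with each other slightly more than cyfluthrin arrays did. The mean correlation across probes was 0.935 between controls (0.895 to 0.981) and 0.900 between cyfluthrin arrays (0.797 to 0.971). The difference of 0.0356 had an exact permutation p of 0.0491 over all splits of the arrays, and of 0.0445 over the 4900 splits within slides, a test added after the data had been seen. It was not past the threshold with normexp and quantile normalization (0.0227, exact permutation p = 0.127), nor after leaving out any array other than control 4, control 8, cyfluthrin 5 or cyfluthrin 6 (exact permutation p of 0.0528 to 0.177). Between a control and a cyfluthrin array the mean correlation was 0.908, so on average cyfluthrin arrays resembled each other no more than they resembled controls. Slides differed more than groups in brightness. The 75th percentile was 338 ± 48.6 units on slide 1 and 572 ± 168 on slide 2 (SD, 8 arrays each, exact permutation p = 0.000311, adjusted over 5 measures 0.00155). Slides also differed in probes above background (6699 ± 344 and 7587 ± 429, exact permutation adjusted p = 0.00194) and in principal components of the arrays. Component 1 (33.9% of variance) had an adjusted p of 0.00544 by the same test, component 3 (11.9%) of 0.0328 and component 2 of 0.895. Between groups no measure passed the adjusted threshold, and the lowest adjusted p was 0.0839 (exact permutation, component 3).

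All control arrays lay in row 1 of their slide and all cyfluthrin arrays in row 2, so slide row and treatment cannot be told apart. The labels do not say whether samples of a group came from separate exposures, so p-values measure the spread between these samples.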

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

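The tests in this part were chosen after the result was seen. Cyfluthrin replicate 7 stood apart in brightness: its 75th percentile of signal was 950 units, while the nearest cyfluthrin array had 577 and the lowest 274. It was the single extreme array among 16 such tests, of which chance gives about 1 in 20. The median signal of its negative control spots was 73.5 units against 39 to 51 on the other 7 cyfluthrin arrays, as a higher background or more non-specific binding on that array would give. More labelled RNA at an equal background would lift all probes by a common factor, but probes below the lower quartile of level rose by 1.498 log2 units more than those above the upper quartile. No biological explanation was tested, since the labels give this sample no property of its own. Without it 163 probes changed (77 rose, 86 fell), 155 of them among the 210, and all 27 of the large rises were called.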

How the results depend on the processing

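Both falling named contigs kept their call under every alternative run; the rising ones lost theirs only within slide 1, and 1 of them was not tested under the filter on all 16 arrays. The count of 210 changed probes became 79 with normexp and the 75th percentile, 347 with the slide as a block, 12 within slide 1 (195 within slide 2, with as many arrays), and 477 at an unadjusted p under 0.05 with at least 1.5-fold change. Leaving out 1 array gave 138 (control replicate 6) to 227. The 27 rises of at least 8-fold became 11 with normexp and quantile normalization, 10 with normexp and the 75th percentile, and 25 to 27 with 1 array left out; within slide 1 all 27 rose by at least 3.36 log2 units but only 1 passed the adjusted threshold. Apart from the looser threshold, the cause was not tested. The similarity difference of 0.0356 became 0.0227 with normexp and quantile normalization, 0.0323 without a filter, and 0.0245 to 0.0429 with 1 array left out. Within slides the share of rises was 25% on slide 1 and 75.9% on slide 2. Other counts stayed within 1.5 times of 210, among them quantile normalization (228), the authors' value table (225, 175 shared), no filter (187), exact rank-sum tests (205, 162 shared) and array weights (282). The same replicate number marks the same slide and slide column in both groups, so it pairs array positions. Whether it also pairs the samples was not settled. Of 8 pairs, 6 correlated above 0.1 (range −0.019 to 0.567), and 6 of 16 arrays correlated best with their own number. No chance level stands beside these counts. With the replicate number as a block 220 probes changed, 156 of them shared. The slide by treatment count was 0 with normexp and quantile normalization too. The gene lists and their alternatives were not run. Signal over background limits the rest: 5673 of 8507 probes were above it on all 16 arrays.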

Other observations

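The tests in this part were chosen after the results were seen, except the regrouping of arrays for the count of 210 and the correlation of probes with consecutive numbers. The 27 probes that rose by at least 8-fold also varied together over the 16 arrays once group means were removed. Their median pairwise correlation was 0.884, while 1000 random lists of matched level had a median of 0.018 and at most 0.190. The 71 smaller rises had 0.120 (random lists at most 0.1005) and the 112 falls 0.132, which 1 of 1000 random lists reached. Random lists came from unchanged probes and were not matched on spread. The set of 27 had an SD of 1.18 between cyfluthrin arrays, against a median of 0.467 over probes tested, so the contrast may be overstated.

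Regrouping the 16 arrays argued against chance for the count of 210. Of 100 splits, only 1, the real one, gave as many as 210 changed probes; the highest other gave 1. For rises of at least 8-fold 1 split, the real one, gave 27 and the highest other 0. That cutoff was picked from the real split, so this second comparison allows no conclusion on chance. Splitting by slide called 1772 probes, 11 of them at least 8-fold, which points to a structure of the samples or of the slides; these were not told apart by any test, and the slides also differed in brightness. The counts within slides and with the slide as a block stand in the report.

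A shift of the treated slide row that acts on all probes alike could not give the set of 27, since scaling removes it. The 5 bright spike-in probes, read before any scaling, showed no such shift (mean rise of 0.0342 log2 units, SE 0.149). A row effect limited to some probes was not tested. The 5 dimmer spike-ins rose by 0.138 to 1.48, less than any of the 27. Within these 27 an effect of a single slide was not seen, since the smallest change of a member on either slide was 2.34 log2 units. Selection on both slides together favours this. Whether the set may come from extra RNA of a fixed composition, such as fragments of a transcript or an added organism, stays open. A first test gave a spread left after probe and array means 2.11 times that between duplicate spots, above the bound of 2 set against this explanation, but duplicate spots miss noise between arrays, so the ratio decides nothing. A second test, with bounds of 1.5 and 3 set after that ratio was seen, gave 2.29 times the spread of the spike-ins (95% interval 1.67 to 2.96) and did not decide it either; handling by group and slide row also stay open beside the exposure.

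Changed probes seemed to cluster by probe number. Only 2 consecutive pairs were both changed, against 2.19 expected (permutation p = 0.65), so the pattern was absent there. Within 20 numbers there were 84 pairs against a random mean of 60.6 (permutation p = 0.00599). That window was picked from the clusters seen, so this p-value is no independent test of them. Consecutive numbers may target related sequences: 2744 unchanged consecutive pairs had a median correlation of 0.110 against 0.066 in random pairs (permutation p = 0.0001, the smallest 10000 permutations can give).

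The closest 2 arrays were control 5 and control 6 (r = 0.981).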
